A study of Homo sapiens with 12 samples.

How the data were processed

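Gene expression was measured on 12 Affymetrix U133 Plus 2.0 arrays in 3 human multiple myeloma cell lines that carry green fluorescent protein (GFP). MM.1S is a myeloma line sensitive to dexamethasone, MM.1R is its dexamethasone-resistant derivative, and INA-6 is a myeloma line that depends on interleukin 6. Each line had spent 24 hours either by itself or together with HS-5, a human bone marrow stromal line without the label, and the GFP-positive cells had then been separated by cell sorting. Each of the 6 groups (3 lines, alone or in coculture) had 2 arrays, which the series text calls technical replicates. The sorted HS-5 cells themselves were not analysed here.

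The values are the deposited intensity of each probe set on a linear scale, as the authors gave them, and no raw scans were used here. How the authors made these values is not settled. Per the submitters' processing notes the tool was MAS5, while the series design text describes normalization and modeling with dChip and averaging of the duplicates. The table holds all 12 arrays separately, and the versions and settings are not given in the sources used here. The median value per array lay between 19.78 and 24.09, and between 3.02% and 3.63% of the values of each array stood at exactly 1. An array gives no counts, so the number of arrays limits the precision.

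The table held 54675 probe sets, of which 1 was left out for a missing value. The array's annotation paired 41097 probe sets with 1 gene symbol, 1801 with several and 11776 with none. For 41043 probe sets the symbol was looked up again by gene ID, and 0 symbols changed. The 62 control probe sets were kept out of all tests. Values were taken to log2 after adding 5, the 20th percentile of all values rounded to a whole number. A probe set was tested if it lay above the median of its own array in at least 2 of the 12 arrays, which 35664 did. Each gene was represented by its tested probe set with the highest mean over the 12 arrays, giving 15052 genes, of which 7212 had several tested probe sets. No coordinates are given, since no genome build is named in the sources used here.

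The effect of coculture common to the lines was fitted with limma 3.58.1 in R 4.3.3. The duplicates of each group were averaged on the log2 scale, leaving 6 values per gene, and the cell line entered as a block, which leaves 2 residual degrees of freedom and a prior of 5.47. In this fit the lines are the replicates, although MM.1R descends from MM.1S. The effect within each line came from a limma fit of all 12 arrays with a mean per group and 6 residual degrees of freedom, in which the 6 groups share an estimate of the spread between duplicates. The differences between the lines were tested in the same fit, by an F-test over the lines and by the contrasts MM.1R minus MM.1S and INA-6 minus the mean of MM.1S and MM.1R. The p-values of this 12-array fit measure only the spread between duplicate arrays. All tests were two-sided moderated tests with Benjamini-Hochberg adjustment over the 15052 genes and a threshold of 0.05. A separate count took genes that changed at least 2-fold the same way in each of the 3 lines, without a test.

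Before the data were examined, 17 gene lists were fixed: responses to interleukin 6 and STAT3, NF-kB targets, interferon-stimulated genes, MHC class I antigen presentation, MYC and its targets, cell cycle, plasma cell identity, the unfolded protein response, hypoxia and glycolysis, cholesterol biosynthesis, apoptosis regulators, adhesion and homing, Notch, glucocorticoid response, immediate-early and heat-shock stress, cytokines secreted by HS-5 cells, and markers of stromal cells. Each was tested with camera of limma at its preset correlation of 0.01, with adjustment over the 17 lists of a contrast. Camera with a correlation estimated from the residuals and the rotation test fry were the alternatives. The median change of a list is given relative to the median of all genes tested. The tests, the grouping and the alternatives were also fixed at that time, except where a sentence says otherwise.

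The genes named were chosen by a rule fixed at the same time. It took the 12 largest rises and 12 largest falls among genes that passed the common test with the same sign in all 3 lines. It also took the 5 largest of each in each line, 2 members of each list, the 4 highest and 4 lowest differences of INA-6 from the other lines, the 3 largest differences of MM.1R from MM.1S, and NR3C1 as a check of the labels. For a list, the members were the 2 largest rises and falls among those passing the test in the common fit, or the 2 largest changes where fewer than 2 passed. Other members of a list are named as examples and were chosen after their values were seen.

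The fits were tested on simulated data of 15052 genes. In a run with 67, 67 and 66 changed genes of log2 size 1, 2 and 4, the common fit recovered 0% at each size with 0 false calls. A run added after seeing that, with sizes 1, 2, 4 and 6 and 50 genes of each, gave 0%, 2%, 50% and 70% for the common fit, again with 0 false calls. The MM.1S contrast recovered 26.9%, 65.7% and 92.4% of the changed genes at sizes 1, 2 and 4 of the earlier run, and the MM.1R contrast 23.9%, 55.2% and 93.9%. The F-test between lines recovered 2.99%, 28.4% and 68.2%. False calls made up 3.91%, 7.26% and 2.94% of the calls of these 3 tests, and INA-6, in which no change was simulated, had 0 calls. Far fewer genes were changed in these runs than the 3381 with unadjusted p under 0.05 in the common fit of the real data. The adjustment was therefore stricter in the runs, and the shares recovered do not give the power of the fits on the real data.

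The alternatives were a pseudocount of 1 or of 14 (the 40th percentile), quantile normalization, centring each array on its median, no filter on dim probe sets, a filter at the 75th percentile, all tested probe sets counted, a mean-variance trend with robust eBayes, leaving out each array or each line in turn, the 12 arrays fitted without averaging, and the replicate number as a block. Leaving the INA-6 arrays out of the fits of MM.1S and MM.1R was added after seeing the data. When a left-out array leaves a group with a lone array, that array is assumed to vary like those of the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.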

Results

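The expression profiles of 3 myeloma lines were compared between cells kept alone and cells sorted after 24 hours with the stromal line HS-5, on 12 arrays. Each combination of line and condition had 2 arrays. The question the design states is how contact with stromal cells changes the profile of each line. Median values per array lay between 19.78 and 24.09, and 75th percentiles between 69.93 and 128.5.

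The groups differed in signs of RNA quality and of labelling. The ratio of 3′ to 5′ signal of the ACTB control probe sets, which rises when transcripts are shortened, was 22.4 ± 0.453 (SD, n = 2) in MM.1S alone and 5.10 ± 0.191 (SD, n = 2) in MM.1S after coculture. In MM.1R it was 31.4 ± 1.16 alone and 5.21 ± 0.285 after coculture (SD, n = 2). In INA-6 it went the other way, with 5.51 ± 0.291 alone and 32.0 ± 0.530 after coculture (SD, n = 2). The GAPDH ratio moved in the same directions, from 5.99 to 1.89 in MM.1S, from 6.51 to 1.71 in MM.1R and from 2.88 to 4.96 in INA-6. The bacterial spike-in BioB, added in a fixed amount, read higher in cells alone, at 1668 against 346 in MM.1S, 529 against 400 in MM.1R and 3329 against 721 in INA-6. The duplicates of INA-6 alone correlated at 0.839 across genes (genes are not independent replicates), and those of the other 5 groups at 0.946 to 0.986.

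**Figure D1:**
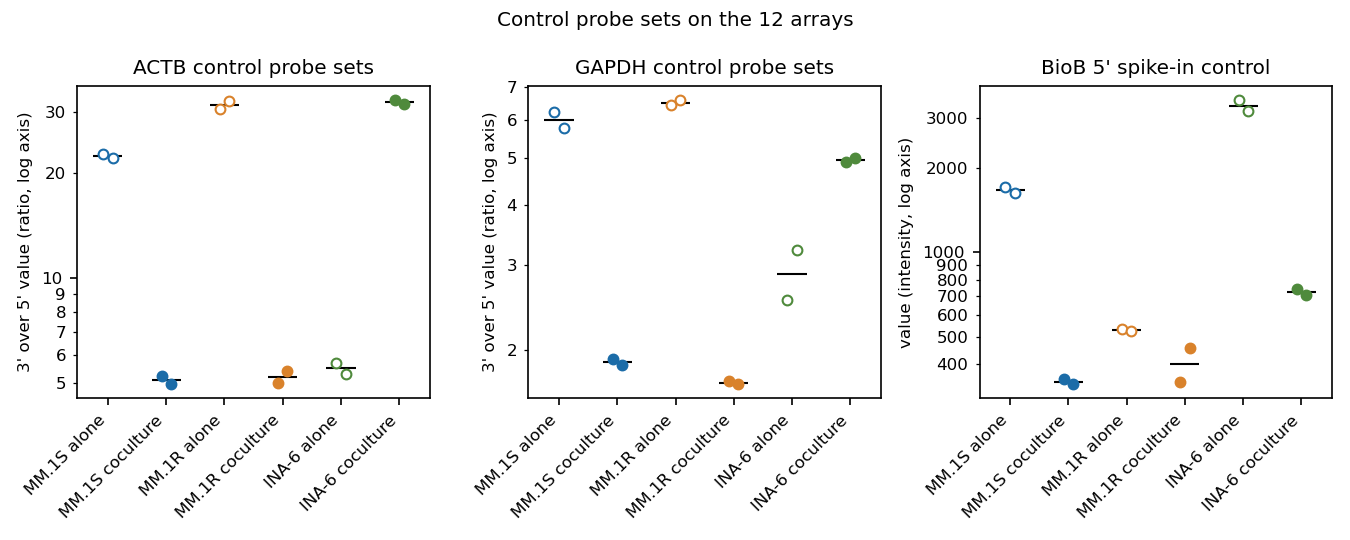
Ratio of 3′ to 5′ signal of the ACTB and GAPDH control probe sets and value of the BioB spike-in, on log axes, for each array (circles; black line, mean of the 2 arrays of a group). The ratio of ACTB lies near 5 in MM.1S and MM.1R after coculture and in INA-6 alone, and at 22.4 to 32.0 in the other 3 groups.

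The largest rises after coculture are given for genes that passed the common test with the same sign in all 3 lines. MMP1, a collagenase that degrades matrix, rose by 8.28 ± 0.43 (log2, SE, n = 6 averaged values; adjusted p = 0.00130), from 13.4 to 6008 in MM.1S, from 11.7 to 8596 in MM.1R and from 29.0 to 5948 in INA-6. The largest rises also held TFPI2, a protease inhibitor of the matrix (8.17 ± 0.45, adjusted p = 0.00130), the collagen VI chains COL6A2 (7.15) and COL6A1 (6.75), the neutrophil chemokine CXCL8 (7.12), the secreted hormone STC1 (6.65) and the matrix protein TGFBI (6.47). TMEM158 (6.44), the G-protein subunit GNG11 (6.43), the tight-junction gene CLDN11 (6.29) and the cytokine IL1A (6.06) followed. IL6, the main growth factor of myeloma cells, rose by 6.39 ± 0.59 (adjusted p = 0.00277), from 16.4 to 2582 in MM.1S, from 24.98 to 5125 in MM.1R and from 68.1 to 1598 in INA-6. Each of these 12 genes was higher in 3 of 3 lines, as the choice required. RNA of HS-5 cells in the sorted fraction stays open as a source of these rises. In cells alone TFPI2, COL6A2, STC1, TGFBI, TMEM158, CLDN11 and IL1A read below the array medians in all 3 lines and MMP1 in 2 of them, so the size and order of the rises depend in part on the pseudocount. Over the alternatives MMP1 ran from 7.77 to 8.68, COL6A2 from 6.38 to 7.71, TMEM158 from 5.52 to 7.21 and IL1A from 5.18 to 6.88, and rises of other genes read low in cells alone have the same limit. In all, 510 of 15052 genes passed the test, 494 higher and 16 lower, each with the same sign in the 3 lines.

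**Figure D2:**
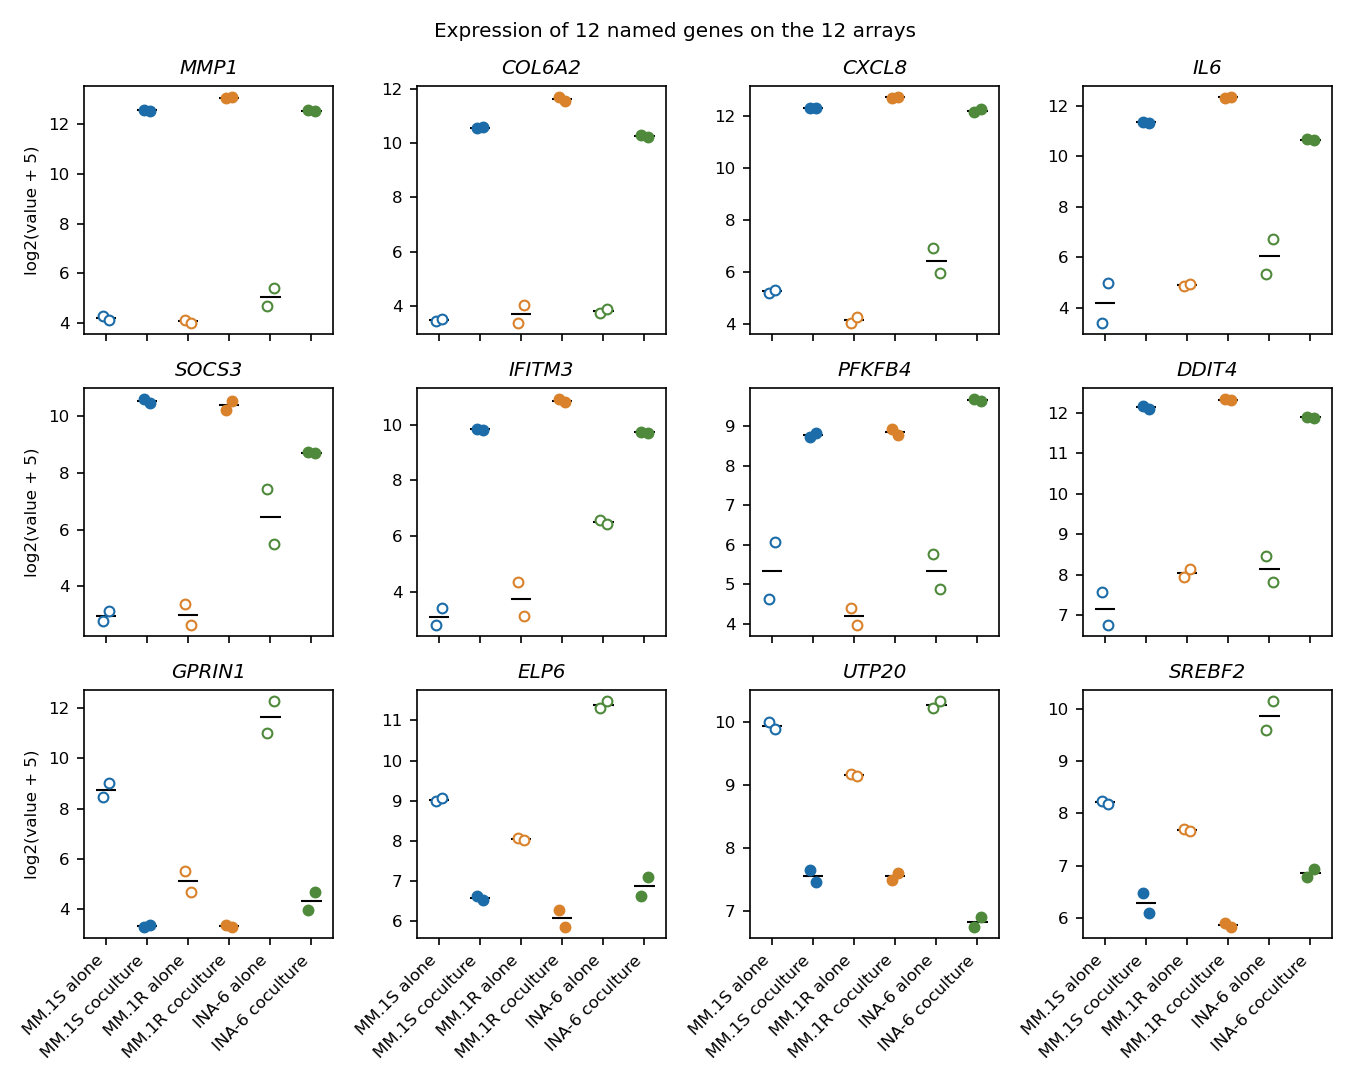
Expression of 12 genes as log2(value + 5) on each array (open circles, cells alone; filled circles, coculture; black line, mean of the 2 arrays of a group). Genes of the top and middle panels were higher after coculture in all 3 lines, and the 4 genes of the bottom panels were lower.

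Cytokines that HS-5 cells secrete were the list with the largest change. Of its 19 measured members, 12 rose, 0 fell and 7 did not pass (14 when adjusted over the list alone), with a median change of 3.83 relative to all genes (camera adjusted p = 1.75e-10; adjusted p = 0.359 with an estimated correlation). Beside IL6 and CXCL8, the neutrophil growth factor CSF3 (5.98), the chemokine CXCL5 (6.01) and the inflammatory cytokine IL1B (5.29) rose. Of 43 markers of stromal cells, 18 rose, 0 fell and 25 did not pass (22 when adjusted over the list alone), with a median of 1.22 (camera adjusted p = 8.78e-08; adjusted p = 0.380 with an estimated correlation). Fibronectin FN1 (4.91), the collagen chain COL1A2 (5.32) and the calcium-binding S100A6 (5.73) rose. Of the contractile genes, the tropomyosins TPM1 (2.70) and TPM2 (2.94) rose, while TAGLN, ACTA2 and MYL9 stood at -0.85, -0.04 and -0.68 on the probe sets used and did not pass. Another probe set stood at 1.03 for TAGLN and 0.87 for MYL9. COL1A1 stood at -0.47 on the probe set used, which did not pass, while 3 of its other probe sets stood at 3.62 to 6.69 and 1 at -0.96.

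Many genes induced by interferon rose. Of 39 members, 14 rose, 0 fell and 25 did not pass (21 when adjusted over the list alone), with a median of 1.33 (camera adjusted p = 2.69e-08; adjusted p = 0.257 with an estimated correlation). IFITM3, which blocks viral entry, rose by 5.70 ± 0.74 and IFI6 by 4.40 ± 0.47, as did the antiviral genes ISG15 (4.31) and MX1 (4.15). Among NF-kB targets 3 of 26 rose and 0 fell (6 when adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.00880; adjusted p = 0.348 with an estimated correlation), led by the chemokine CCL20 (5.96) and the early-response gene IER3 (5.24). Of 22 genes of the interleukin 6 and STAT3 response, 4 rose and 0 fell (7 when adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00496; adjusted p = 0.257 with an estimated correlation). SOCS3, the feedback inhibitor of this pathway, rose by 5.73 ± 0.97 (adjusted p = 0.0281) and the oncostatin M receptor OSMR by 3.97 ± 0.48. STAT3 itself stood at 0.82, which did not pass. In MHC class I presentation 0 of 16 members passed (0 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.118) and with the proteasome subunits PSMB8 and PSMB10 at 1.71 and 1.02. Stromal markers rose in the same comparison as these lists, by the median of 1.22 given above.

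Genes of hypoxia and glycolysis moved together. Of 28 members 12 rose, 0 fell and 16 did not pass (19 when adjusted over the list alone), with a median of 1.59 (camera adjusted p = 3.18e-10; adjusted p = 0.257 with an estimated correlation). PFKFB4, a regulator of glycolysis, rose by 4.14 ± 0.41 and the mitophagy gene BNIP3 by 3.55 ± 0.54, with NDRG1 (3.42) and the hexokinase HK1 (3.32). Of 26 immediate-early and heat-shock genes 12 rose and 0 fell (19 when adjusted over the list alone), with a median of 1.75 (camera adjusted p = 1.18e-07; adjusted p = 0.257 with an estimated correlation). The chaperone HSPB1 rose by 4.14 ± 0.63, and the phosphatase DUSP1 by 3.91, though the 3 probe sets of DUSP1 ran from -1.33 to 3.91. Of 11 genes of the glucocorticoid response 3 rose and 0 fell (5 when adjusted over the list alone), with a median of 1.13 (camera adjusted p = 5.05e-05; adjusted p = 0.257 with an estimated correlation). These were ERRFI1, an inhibitor of the EGF receptor (4.91 ± 0.48), the mTOR inhibitor DDIT4 (4.33 ± 0.41) and DUSP1. All 3 lists moved in the same direction in lines whose ACTB ratios moved in opposite directions. BioB read lower after coculture in all 3 lines, and stromal markers rose in the same comparison (median 1.22).

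Of 24 apoptosis regulators 2 rose and 0 fell (6 when adjusted over the list alone), with a median of 0.81 (camera adjusted p = 0.00496; adjusted p = 0.380 with an estimated correlation). Both were anti-apoptotic members of the BCL2 family, BCL2A1 (3.40 ± 0.41) and BCL2L2 (2.15 ± 0.45, adjusted p = 0.0492). Pro-apoptotic members of the family also stood higher without passing, as BAX at 2.21 and PMAIP1 at 1.85, while BIK and HRK stood at -0.22 and -0.97. Of all 24 regulators 20 stood above 0, so the 2 calls do not show an anti-apoptotic shift of the list. Cholesterol biosynthesis had a lower median, at -0.44 over 17 members, of which 1 fell and 0 rose (1 when adjusted over the list alone; camera adjusted p = 0.00785; adjusted p = 0.257 with an estimated correlation). The member that fell was SREBF2, a regulator of the pathway, and the enzyme MSMO1 stood at -1.36 without passing. The other lists did not pass. In the unfolded protein response (median 0.25, camera adjusted p = 0.171) 2 of 22 members rose and 0 fell (3 when adjusted over the list alone), CHAC1 (2.66 ± 0.39) and PPP1R15A (2.54 ± 0.38). In plasma cell identity (median 0.20, camera adjusted p = 0.489) 1 of 18 rose (1 when adjusted over the list alone), KLF13 (2.25), with the plasma cell factor IRF4 at 1.36. In the cell cycle (median 0.21, camera adjusted p = 0.408) 0 of 32 passed (0 when adjusted over the list alone), with CDC6 at -2.03 and PLK1 at 1.88. Of 23 MYC targets 1 fell (2 when adjusted over the list alone; camera adjusted p = 0.116), UTP20, and the transferrin receptor TFRC stood at -1.66. This list's median was 0.09 before and -0.17 after subtracting that of all genes, and its mean was -0.08. In adhesion and homing 1 of 27 rose (1 when adjusted over the list alone), CD99 (3.32), with CD9 at 1.84. Its median was -0.07 relative to all genes, and camera's direction was up (adjusted p = 0.948). In the Notch list 1 of 12 rose (1 when adjusted over the list alone), HEY2 (2.41), with NOTCH3 at -1.33 (median -0.02, camera adjusted p = 0.853).

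Falls were few and smaller. The 12 largest were GPRIN1 (-4.82 ± 0.91, adjusted p = 0.0392), the vesicle protein VAMP1 (-3.79 ± 0.63), the Wnt ligand WNT2B (-3.67 ± 0.74), ELP6 (-2.98 ± 0.55), SNX8 (-2.89), DPP3-DT (-2.55), LINC00174 (-2.54), the potassium channel subunit KCNV1 (-2.51), the centrosomal CNTRL (-2.51), UTP20 (-2.48), SREBF2 (-2.25) and C22orf42 (-2.23). GPRIN1 went from 434 to 5.16 in MM.1S, from 30.9 to 5.14 in MM.1R and from 3442 to 15.9 in INA-6. Of the 16 genes lower, 11 had another tested probe set. In 9 of them another probe set had the opposite sign, as in GPRIN1 (0.07), VAMP1 (1.03), CNTRL (0.68), ELP6 (0.50) and SREBF2 (0.52), and in 2 another probe set was also at least 2-fold lower. Of the 494 genes higher, 234 had another tested probe set, at least 2-fold higher in 152 and of the opposite sign in 73. Among these 73 were CLDN11, COL6A1, SOCS3, BCL2L2, KLF13, HEY2 and DUSP1.

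The common test used limma on the 6 averaged values with the line as block, and 3381 genes had an unadjusted p under 0.05. The count of 510 was 258 without replicate 1 of INA-6 alone, 247 after quantile normalization, 303 with each array centred on its median, 3660 without INA-6 and 7778 when the 12 arrays were fitted without averaging. Adjusted p of each of the 12 falls went above 0.05 under at least 1 alternative, up to 0.0552 for VAMP1 and up to 0.107 for C22orf42, and the same held for SOCS3 (up to 0.0627), CHAC1 (0.0668), HEY2 (0.0852), KLF13 (0.117) and BCL2L2 (0.159). The median of all genes was itself 0.27 higher after coculture, and 0.02 after quantile normalization or -0.01 after centring. The 10 lists that passed kept their direction and their call under both scalings, MYC targets fell after quantile normalization (-0.25, adjusted p = 0.0315), and the Notch median turned to 0.03 after quantile normalization.

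In MM.1S, the largest rises after coculture were MMP1 (8.35 ± 0.22, log2, SE, adjusted p = 1.62e-06), TFPI2 (7.67 ± 0.35), SOCS3 (7.57 ± 0.55), IL6 (7.13 ± 0.54) and COL6A2 (7.09 ± 0.21). In this line and the others, RNA of HS-5 cells in the sorted fraction stays open as a source of such rises. SOCS3 went from 2.86, near the floor of 1, to 1473, so its rise depends on the pseudocount (6.46 to 8.63 over the alternatives). The largest falls were MFSD6L, a membrane transporter family gene (-5.75 ± 0.64, adjusted p = 0.000343), GPRIN1 (-5.41 ± 0.46), WNT2B (-4.21 ± 0.65), VAMP1 (-4.03 ± 0.78) and DPP3-DT (-3.30 ± 0.79). MFSD6L read 1.27 after coculture, near the floor of 1, so its fall depends on the pseudocount (-7.19 to -4.51 over the alternatives). Of 16 genes of MHC class I presentation 14 rose and 0 fell, 14 when adjusted over the list alone (median 1.32, camera adjusted p = 1.69e-06; adjusted p = 0.0486 with an estimated correlation), among them HLA-B (2.26). Of 22 genes of the unfolded protein response 18 rose and 1, HSP90B1, fell by 1.05 on the log2 scale; 19 passed when adjusted over the list alone (median 1.08, camera adjusted p = 3.94e-06; adjusted p = 0.0452 with an estimated correlation). Of 18 plasma cell genes 13 rose and 0 fell, and 15 passed when adjusted over the list alone, 14 of them higher (median 0.71, camera adjusted p = 0.000604; adjusted p = 0.0486 with an estimated correlation), among them IRF4 (2.15) and XBP1 (1.25). The plasma cell median was 0.44 after quantile normalization (camera adjusted p = 0.0398).

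The lists of HS-5 cytokines (median 3.81), immediate-early and heat-shock genes (1.74), hypoxia (1.61), interferon (1.56), glucocorticoid response (1.54), stromal markers (1.53), the interleukin 6 and STAT3 response (0.94) and apoptosis (0.89) were also higher in MM.1S, with camera adjusted p of 1.69e-06, 5.77e-06, 9.62e-08, 6.66e-07, 0.000506, 5.77e-06, 0.00369 and 0.0197. With an estimated correlation hypoxia gave adjusted p = 0.102, the STAT3 response adjusted p = 0.0543 and apoptosis adjusted p = 0.391, and the other 5 stayed under 0.05. Cholesterol genes, with camera adjusted p = 0.0544, passed as lower after quantile normalization (0.00894) and after centring (0.0343). Members that rose were 13, 18, 21, 23, 8, 25, 11 and 10 in that order, and 14, 18, 23, 25, 9, 25, 11 and 11 when adjusted over the list alone; 1 HS-5 cytokine and 1 apoptosis regulator fell. In MM.1S 25 of the stromal markers thus moved with these lists, and the ACTB ratio fell from 22.4 to 5.10. In all, 4858 genes passed, 3604 higher and 1254 lower. The share higher, 74.2%, was 58.3% after quantile normalization and 63.5% after centring. The p-values of this fit and of the fits per line that follow measure only the spread between duplicate arrays, stated to be technical. The count was 2918 or 2945 without replicate 1 or 2 of MM.1S coculture, 7897 without either array of INA-6 alone, which enters through the shared spread, and 7582 without all INA-6 arrays, an alternative added after seeing the data.

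In MM.1R, the largest rises were TFPI2 (9.14 ± 0.35, adjusted p = 2.96e-06), MMP1 (9.01 ± 0.22), CXCL8 (8.56 ± 0.28), COL6A2 (7.91 ± 0.21) and TGFBI (7.72 ± 0.25). Falls were led by the MHC class II chain HLA-DQA1 (-3.44 ± 0.70, adjusted p = 0.0126), the chemokine receptor CXCR3 (-2.70 ± 0.26, adjusted p = 0.000375), the dynein chain DNAH17 (-2.69 ± 0.64, adjusted p = 0.0244), the potassium channel KCNA3 (-2.46 ± 0.42) and the inositol kinase ITPK1 (-2.36 ± 0.31). Of 17 cholesterol genes 6 fell and 2 rose, 8 passing when adjusted over the list alone (median -0.43, camera adjusted p = 0.00525; adjusted p = 0.0444 with an estimated correlation). Of 22 genes of the unfolded protein response 14 rose and 1 fell, 17 passing when adjusted over the list alone (median 0.67, camera adjusted p = 5.02e-07; adjusted p = 0.0277 with an estimated correlation), among them HSPA5, the main chaperone of the endoplasmic reticulum (1.44). Of 16 genes of MHC class I presentation 9 rose and 0 fell, 13 when adjusted over the list alone (median 0.49, camera adjusted p = 3.47e-05; adjusted p = 0.0512 with an estimated correlation).

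The lists of HS-5 cytokines (15 of 19 rose, 16 when adjusted over the list alone, median 5.27, camera adjusted p = 2.04e-16) and stromal markers (29 of 43 rose, 30 when adjusted over the list alone, median 2.12, camera adjusted p = 8.26e-16) led in MM.1R. Immediate-early and heat-shock genes (1.68), hypoxia (1.63), interferon (1.5), glucocorticoid response (1.47), the STAT3 response (0.65), apoptosis (0.37) and NF-kB targets (0.25) were also higher, and MYC targets were lower (-0.30, with 4 rising and 4 falling). Members that rose in these higher lists were 16, 20, 22, 6, 8, 6 and 7 in that order, and 16, 21, 23, 7, 8, 7 and 9 when adjusted over the list alone, and 1 NF-kB target fell. Their camera adjusted p were 5.99e-11, 3.29e-13, 1.50e-12, 7.04e-05, 0.000277, 0.0207, 0.0195 and 0.00712. With an estimated correlation the call was lost for hypoxia and for NF-kB (adjusted p = 0.0512 for each), apoptosis (adjusted p = 0.381) and MYC targets (adjusted p = 0.180). In all, 2417 genes passed, 2001 higher and 416 lower. The share higher, 82.8%, was 60.4% after quantile normalization and 66.4% after centring. The ACTB ratio fell from 31.4 to 5.21 in this line. The count was 1066 to 1272 without any of the 4 MM.1R arrays in turn, 5501 without either array of INA-6 alone and 5134 without all INA-6 arrays, an alternative added after seeing the data. DNAH17 (up to 0.165) and HLA-DQA1 (up to 0.0816) lost their calls under some alternatives, and HLA-DQA1 had another probe set with a common change of 0.24.

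In INA-6, the largest rises were TFPI2 (7.71 ± 0.35, adjusted p = 6.62e-06), MMP1 (7.49 ± 0.22), COL6A2 (6.45 ± 0.21), STC1 (6.01 ± 0.34) and COL6A1 (5.97 ± 0.48). Among the 5 largest falls, NOTUM, a secreted inhibitor of Wnt signalling, went from 5186 to 4.80 (-9.04 ± 0.34, adjusted p = 4.67e-06), MFSD6L from 3243 to 2.66 (-8.54 ± 0.64), LINC03024 from 1592 to 1 (-8.01 ± 0.22), GPRIN1 fell by 7.28 on the log2 scale, and the Wnt co-receptor PTK7 went from 3440 to 42.5 (-6.08 ± 0.86). Another probe set of PTK7 had a common change of 0.72, against -3.10 on the one used. Values after coculture near the floor of 1 leave the size of a fall to the pseudocount: over the alternatives NOTUM ran from -9.86 to -8.08, MFSD6L from -9.61 to -7.42 and LINC03024 from -9.60 to -6.70. Of 22 genes of the unfolded protein response 12 fell and 4 rose, 16 passing when adjusted over the list alone (median -0.93, camera adjusted p = 0.00522; adjusted p = 0.168 with an estimated correlation, and camera adjusted p = 0.0515 after quantile normalization). HSPA5 stood at -1.34 and HSP90B1 at -1.25, both called. Of 27 adhesion genes 7 fell and 5 rose, 12 when adjusted over the list alone (median -0.75, camera adjusted p = 0.0209; adjusted p = 0.117 with an estimated correlation), among them the integrin ITGB7 (-1.59) and PECAM1 (-1.65). Of 17 cholesterol genes 9 fell and 3 rose, 12 when adjusted over the list alone (median -1.05, camera adjusted p = 0.00644; adjusted p = 0.117 with an estimated correlation).

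Hypoxia genes rose in INA-6 too, 24 of 28 (median 1.59, camera adjusted p = 0.000175; adjusted p = 0.217 with an estimated correlation), as did HS-5 cytokines (13 of 19, 2.91, camera adjusted p = 0.00772; adjusted p = 0.217 with an estimated correlation) and the glucocorticoid response (8 of 11, 2.47, camera adjusted p = 0.00772; adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, 24, 14 and 8 members of these lists rose. Immediate-early genes (17 of 26, 1.49, camera adjusted p = 0.0117; adjusted p = 0.117 with an estimated correlation), apoptosis regulators (18 of 24, 0.99, camera adjusted p = 0.0218; adjusted p = 0.405 with an estimated correlation) and interferon genes (23 of 39, 0.65, camera adjusted p = 0.0219; adjusted p = 0.183 with an estimated correlation) were also higher, with 17, 18 and 23 members rising when adjusted over the list alone. Members that fell were 2 immediate-early genes, 3 apoptosis regulators, 2 interferon genes and 1 HS-5 cytokine, and 0 in hypoxia and the glucocorticoid response. MYC targets were lower (7 fell and 3 rose, -0.44 relative to all genes and 0.03 before that, with a mean of -0.25; camera adjusted p = 0.0122; adjusted p = 0.217 with an estimated correlation). Stromal markers (22 rose, 2 fell) and NF-kB targets (16 rose, 2 fell) each had camera adjusted p = 0.0533, and both passed as higher after quantile normalization (0.0276 and 0.0460) and after centring (0.0191 and 0.0313). MHC class I presentation was lower after centring alone (camera adjusted p = 0.0170, against 0.122 before and 0.339 after quantile normalization). The ACTB ratio rose from 5.51 to 32.0 in this line. The arrays of INA-6 alone had the lowest correlation between duplicates (0.839) and the highest BioB (3329), and the profile of INA-6 after coculture correlated at 0.762 with INA-6 alone against 0.898 and 0.895 with MM.1S and MM.1R after coculture. It also correlated at 0.801 with MM.1S alone and 0.850 with MM.1R alone. INA-6 alone was the profile apart, at 0.667 to 0.712 with the groups of MM.1S and MM.1R. In INA-6, MMP1 and BioB moved the same way as in the other lines, and of 37 stromal markers and cytokines called higher in MM.1S and MM.1R, 32 were called higher in INA-6 and 0 lower, which an exchange of the alone and coculture labels would turn around. These data do not settle whether the handling of INA-6 differed, which bears on every change in INA-6 and every difference of INA-6 from the other lines. In all, 7860 genes passed, 5882 higher and 1978 lower. The share higher, 74.8%, was 60.7% after quantile normalization and 55.3% after centring, and the median of all genes was 0.47, 0.16 and 0.02 in these 3 scalings.

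**Figure D3:**
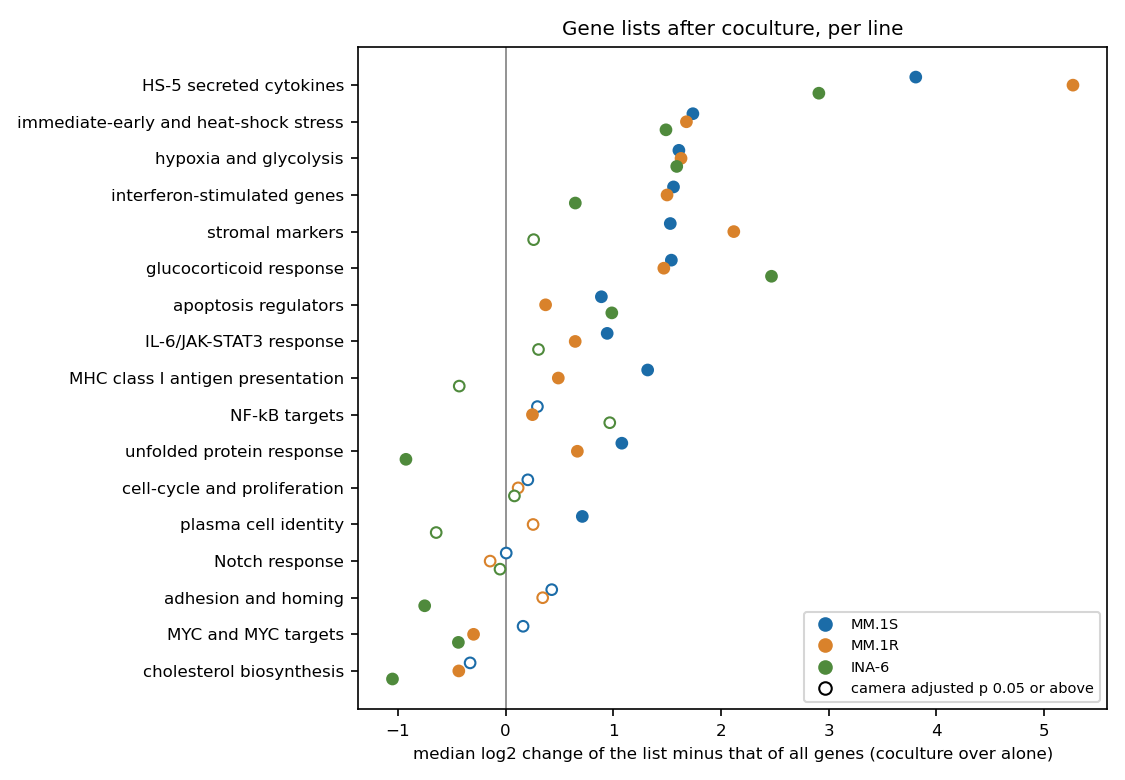
Median log2 change after coculture of each of the 17 gene lists minus that of all genes, per line (filled, camera adjusted p under 0.05). HS-5 cytokines lie at 3.81, 5.27 and 2.91 in MM.1S, MM.1R and INA-6, and the unfolded protein response lies at 1.08, 0.67 and -0.93 (the last without a call after quantile normalization).

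The lines were then compared with each other in their response. The contrast of INA-6 with the other lines follows RNA quality, since the ACTB ratio fell from 22.4 to 5.10 in MM.1S and from 31.4 to 5.21 in MM.1R and rose from 5.51 to 32.0 in INA-6. The matrix protease inhibitor TIMP1 rose by 5.07 in MM.1S and 7.19 in MM.1R, while in INA-6 it stood at 1284 alone and 1578 after coculture (difference of INA-6 from the other lines -5.83, adjusted p = 2.23e-05). NOTUM (-8.40), LINC03024 (-8.01) and RPL39L (-5.60) had the other lowest differences. NOTUM and LINC03024 read 1 to 12.6 in MM.1S and MM.1R, near the floor, where a fall would not show in full. The highest were NARS2-AS1 (6.47, adjusted p = 0.00305), the tRNA methyltransferase TRMT13 (5.29, adjusted p = 2.85e-05), GIGYF1 (5.26) and the endosomal RAB11FIP3 (5.07). In these 4 genes INA-6 alone read 10.6, 11.5, 12.1 and 9.96, against 174 to 615 in MM.1S alone. Against MM.1S, MM.1R differed by 4.93 in MFSD6L (adjusted p = 0.0398), by 3.64 in GPRIN1 (adjusted p = 0.0380) and by -3.42 in TRAPPC1, a subunit of a vesicle tether (adjusted p = 0.0238). MFSD6L read 7.18 in MM.1R alone and GPRIN1 went from 30.9 to 5.14 there, near the floor, which limits the fall that MM.1R could show in both. The calls of MFSD6L and GPRIN1 were lost under several alternatives (adjusted p up to 0.205 for each), as was that of TRAPPC1 (up to 0.190).

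Genes of the unfolded protein response differed between INA-6 and the other lines by a median of -1.61 (14 of 22 lower, 0 higher; camera adjusted p = 3.64e-08; adjusted p = 0.0801 with an estimated correlation), and by -0.98 after quantile normalization. MHC class I presentation followed at -1.17 (10 of 16 lower; camera adjusted p = 5.98e-06; adjusted p = 0.0812 with an estimated correlation), and stood at -0.64 after quantile normalization. HS-5 cytokines stood at -1.65 (camera adjusted p = 5.66e-05; adjusted p = 0.0962 with an estimated correlation) and stromal markers at -1.07 (camera adjusted p = 0.000563; adjusted p = 0.0801 with an estimated correlation). In MM.1R against MM.1S, HS-5 cytokines were higher by 1.18 (camera adjusted p = 2.04e-09; adjusted p = 0.0496 with an estimated correlation) and stromal markers by 0.81 (camera adjusted p = 1.88e-08; adjusted p = 0.0295 with an estimated correlation). MHC class I presentation was lower by a median of -0.63 (camera adjusted p = 3.78e-05; adjusted p = 0.125 with an estimated correlation) and plasma cell identity by -0.59 (camera adjusted p = 3.78e-05; adjusted p = 0.0496 with an estimated correlation). After quantile normalization these stood at -0.46 and -0.20 (camera adjusted p = 0.000312 and 0.00891). The F-test over the 3 lines passed 5379 genes, of which 197 were also among the 510 of the common test. The contrast of INA-6 with the mean of the other lines passed 5894 genes, 3749 with a higher and 2145 with a lower change, and MM.1R against MM.1S passed 370, 85 higher and 285 lower. The F-test count was 9464 without replicate 1 of INA-6 alone, and 3346 or 3273 without replicate 1 or 2 of INA-6 coculture; the count of 370 was 2479 without the INA-6 arrays, an alternative added after seeing the data. Across genes, the changes correlated at 0.77 between MM.1S and MM.1R, 0.391 between MM.1S and INA-6 and 0.331 between MM.1R and INA-6, and genes are not independent replicates.

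**Figure D4:**
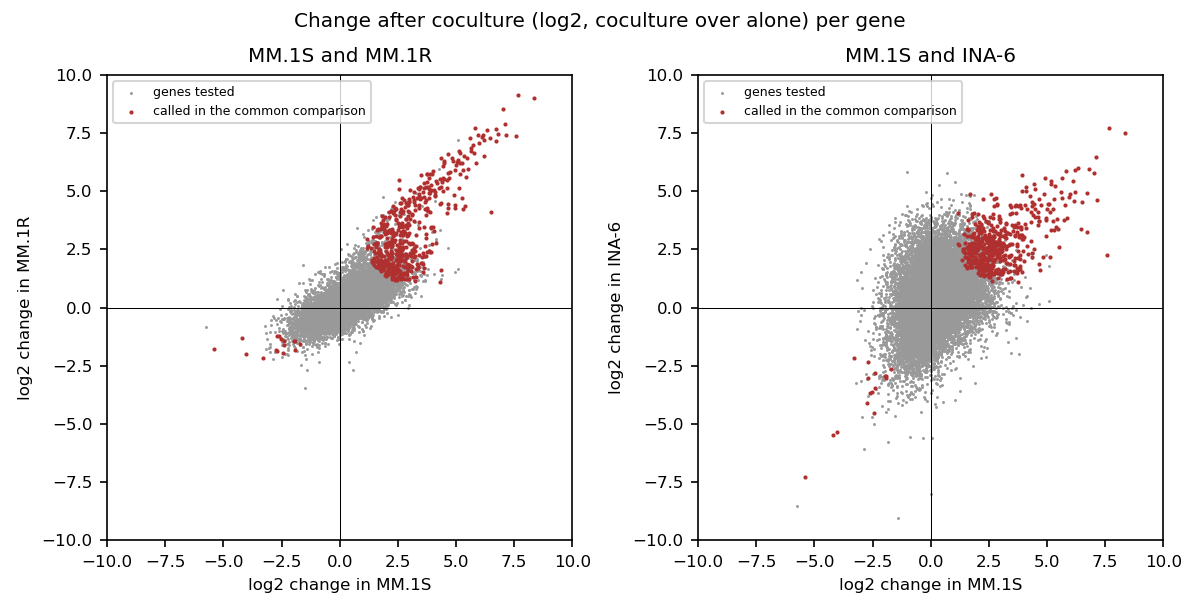
Log2 change after coculture of each of the 15052 genes in MM.1S (horizontal) against MM.1R or INA-6 (vertical), with the 510 genes of the common test in red. The cloud is narrow for MM.1R (correlation across genes 0.77) and wide for INA-6 (0.391).

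Genes that passed in all 3 lines numbered 1097 higher and 120 lower, against 187 and 4.55 expected if the calls in the lines were independent. They could not be independent, since the lines share an estimate of the spread of each gene and MM.1R descends from MM.1S. The excess over these expected counts therefore does not measure a shared response. In opposite directions, 12 genes passed in MM.1S and MM.1R, 657 in MM.1S and INA-6, and 301 in MM.1R and INA-6. Changes of at least 2-fold in the same direction in all 3 lines, a count without a test, were seen in 1048 genes, 974 higher and 74 lower. The share higher, 92.9%, was 81.3% after quantile normalization and 76.6% after centring. The count was 2296 without MM.1R and 1761 without INA-6, where fewer lines had to meet it.

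NR3C1, the glucocorticoid receptor, was looked at as a check of the labels, since MM.1R is resistant to dexamethasone. Cells alone read 970 in MM.1S, 496 in MM.1R and 83.6 in INA-6. After coculture the values were 943, 528 and 479. Its change was -0.04 in MM.1S and 0.09 in MM.1R, neither passing, and 2.45 ± 0.15 in INA-6 (adjusted p = 1.25e-05).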

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

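The tests of explanations in this part were chosen after the results were seen, while the tests between the lines and the gene lists were planned before the data were examined.

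Of 43 stromal markers 18 rose after coculture, and of 19 HS-5 cytokines 12, though neither list passed with an estimated correlation (adjusted p = 0.380 and 0.359). A difference in RNA integrity as the whole cause is argued against, since 32 of the 37 members called higher in MM.1S and MM.1R were also called higher in INA-6, where the ACTB ratio moved the opposite way, and 0 were called lower. Of all 1709 genes called higher in MM.1S and MM.1R, 1097 were called higher in INA-6 too, so such agreement is not particular to these lists. The stromal median relative to all genes was 1.22 as deposited and 1.29 after quantile normalization. This measure leaves out a shift shared by all genes, so it cannot judge the scaling of the arrays as a whole. It shows only that the rise relative to other genes did not depend on that rescaling. RNA of HS-5 cells in the sorted fraction stays open: over 32 members raised at least 4-fold in MM.1S and MM.1R, the excess after coculture was higher in MM.1R for every member, with a spread of 0.342 (SD, log2) around 1.24 and medians of 1.34 for stromal markers and 1.15 for cytokines, as a single share of foreign RNA per array could give. The sort on GFP should remove such cells, and no profile of HS-5 cells alone was used here. Of the 43 stromal markers 33 stood above 0 in the common fit. TIMP3 stood at -0.80 to -0.66 on its probe sets while FN1 reached 1217, 2857 and 1117 in the 3 lines. Over their probe sets CALD1 ran from -0.65 to 2.47, CCN1 from 0.56 to 4.91, THBS1 from -0.36 to 4.20 and COL1A1 from -0.96 to 6.69. The choice of probe set thus hides some stromal rises. On the probe set used, 30 of the 43 stromal genes and 8 of the 19 cytokine genes already lay above the array median in cells alone of at least 1 line. The share over all genes tested was not computed, and the filter and choice of probe set favour such readings. These counts therefore do not show that the myeloma cells express the genes. Induction of these genes in the myeloma cells by contact with HS-5, the biological explanation the design gives, stays open and untested.

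Of 28 hypoxia genes 12 rose in the same comparison, and of 39 interferon genes 14, though neither list passed with an estimated correlation (adjusted p = 0.257 for each). HS-5 RNA as the whole source, with 1 profile in both cocultures, stays open. It was examined by the log2 ratio of the excess after coculture, MM.1R over MM.1S. The excess subtracts cells alone, where the GAPDH 3′ control read 3946 and 3628 in MM.1S against 6837 and 6915 in MM.1R. A weaker reading of MM.1S alone would enlarge its excess for genes the myeloma cells already express, so the ratio cannot decide. It lay below that of the lowest stromal marker (0.535) in 8 of 21 members. Their median was lower by 0.662 than that of the stromal markers (two-sided permutation test, p = 0.00024). That test shuffled list labels over genes of the same arrays. Genes are not independent replicates, so its p measures no spread between arrays or cultures. All 388 genes raised at least 4-fold in MM.1S and MM.1R had a median of 0.989, against 1.34 for the stromal markers. The hypoxia median relative to all genes was 1.59 as deposited and 1.499 after quantile normalization, a measure that has the same limit and cannot judge scaling as a whole. A part or all of the rise may come from HS-5 RNA, and HS-5 cells might respond differently to each line. The ratio also lay below 0.535 in CXCL8, a cytokine (0.429), and in 134 of the 388 genes of all kinds so raised. A response of the myeloma cells to coculture is therefore a hypothesis here, found and tested on the same data.

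The 16 genes lower in the common test read 152 (LINC00174) to 3964 (CNTRL) in INA-6 alone. In MM.1R alone some read close to the array medians of 19.78 and 22.8, with LINC00174 at 21.6, GPRIN1 at 30.9 and C22orf42 at 32.9. Among cells alone, 15 of the 16 followed the order of the BioB spike-in, with INA-6 above MM.1S above MM.1R, against 23.7% of all genes tested and 53 of the 74 genes at least 2-fold lower in all 3 lines. Weak sample signal in the arrays of cells alone, which would raise nonspecific probe sets, is thus a candidate explanation that stays open, and 9 of the 11 genes with another tested probe set had a probe set of the opposite sign. The CreX spike-in, at 8543 to 11507 over all arrays, lacked the wide differences of BioB. RNA integrity as a cause stays open too. Of these 16 genes 14 were called lower in INA-6 by its own arrays, where the ACTB ratio moved the opposite way. The common fit that chose them used the INA-6 values, so their direction there was largely fixed by the choice. Of 316 genes called lower in MM.1S and MM.1R, a choice made without INA-6, 120 were called lower and 106 higher in INA-6. A biological fall stays open and untested.

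The 6 averaged values can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05; 1 split, the real one, passed 510 genes, and the highest of the others passed 0, the 3 others among the 4 splits that part all 3 lines included.

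The response to coculture was tested for differences between the lines, against the spread of duplicate arrays stated to be technical, so that differences between single cultures are not told from differences between lines. The F-test over the 3 lines passed 5379 genes, INA-6 against the mean of the other lines 5894, and MM.1R against MM.1S 370. The ACTB ratio fell from 22.4 to 5.10 in MM.1S and from 31.4 to 5.21 in MM.1R and rose from 5.51 to 32.0 in INA-6, so the differences of INA-6 go along with RNA quality. Lists lower in INA-6 than in the other lines, as medians relative to all genes, were HS-5 cytokines (-1.65), unfolded protein response (-1.61; -0.98 after quantile normalization), MHC class I (-1.17; -0.64 after quantile normalization), stromal markers (-1.07), interferon (-0.98), plasma cell identity (-0.93; -0.29, camera adjusted p = 0.0757, after quantile normalization), the STAT3 response (-0.83; -0.67, adjusted p = 0.141, after quantile normalization), adhesion (-0.72) and MYC targets (-0.71; 0.0019, adjusted p = 0.511, after quantile normalization). With an estimated correlation their adjusted p ran from 0.0801 to 0.239. In MM.1R against MM.1S, HS-5 cytokines (1.18) and stromal markers (0.81) were higher, and MHC class I (-0.63), plasma cell identity (-0.59), MYC targets (-0.49) and the cell cycle (-0.33) were lower. After quantile normalization these 4 stood at -0.46, -0.20, -0.33 and -0.26, the last pair with adjusted p = 0.154. With an estimated correlation the adjusted p of these 6 lists were 0.0496, 0.0295, 0.125, 0.0496, 0.229 and 0.494.

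Among the genes named, log2 differences of INA-6 from the mean of the other lines were as follows. The rise was smaller in INA-6 for MMP1 at -1.18, COL6A2 at -1.05, CXCL8 at -2.03, TGFBI at -0.91, GNG11 at -2.28, IL6 at -2.66, CLDN11 at -1.27, IL1A at -2.20, CCL20 at -1.497, IER3 at -1.20, ERRFI1 at -1.57 and TIMP1 at -5.83. TFPI2 (-0.70, adjusted p = 0.233), COL6A1 (-1.16, 0.155) and STC1 (-0.96, 0.0992) did not pass. A lower difference was also seen in SOCS3 (-5.22), OSMR (-1.53), IFITM3 (-3.71), IFI6 (-1.40), PSMB8 (-1.44), HSPB1 (-2.94) and TRAPPC1 (-0.99). INA-6 had the lower change in GPRIN1 (-3.69), WNT2B (-2.72), ELP6 (-2.31), CNTRL (-1.77), UTP20 (-1.45), SREBF2 (-1.14), TFRC (-0.67), CDC6 (-2.07), MFSD6L (-5.26), NOTUM (-8.40), LINC03024 (-8.01), PTK7 (-4.48) and RPL39L (-5.60). NOTUM and LINC03024 read 1 to 12.6 in MM.1S and MM.1R, and MFSD6L read 7.18 in MM.1R alone, near the floor of 1, so these differences are limited by the floor. SOCS3 read 2.86 and 3.31 and IFITM3 3.75 and 9.53 in MM.1S and MM.1R alone, so the size of their differences depends on the pseudocount. Higher differences were seen in NARS2-AS1 (6.47), TRMT13 (5.29), GIGYF1 (5.26), RAB11FIP3 (5.07), KCNA3 (4.56), ITPK1 (2.60), DNAH17 (2.52), NR3C1 (2.42), HEY2 (1.75) and KLF13 (0.62). PLK1 differed by -1.64 between MM.1R and MM.1S. By the F-test alone, TMEM158 (adjusted p = 0.0356), CXCR3 (0.0496), PSMB10 (0.0458) and IRF4 (0.0238) differed between the lines.

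Control probe sets, outside the main measurement, gave 3′ to 5′ ratios of 32.0 for ACTB and 4.96 for GAPDH in INA-6 after coculture, above those of INA-6 alone (5.51 and 2.88). The direction is opposite to that in MM.1S and MM.1R, whose ratios alone were 22.4 and 31.4 for ACTB and 5.99 and 6.51 for GAPDH.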

How the results depend on the processing

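Leaving all INA-6 arrays out of the line fits was the only alternative chosen after the data were seen. Over the named genes and their alternatives, 2003 values kept direction and side of the threshold, 119 lost the call, 30 gained it and 0 reversed. Each gene was followed on the probe set of the main fit, so another probe set could not count as a reversal. Most of these genes were also chosen for large changes, which made a reversal unlikely. Another probe set had the opposite sign in 9 of 11 genes lower and 73 of 234 genes higher that had one. The common count of 510 became 247 after quantile normalization, 303 with centring, 7778 with 12 arrays not averaged and, from these, 3763 with the replicate number as a block; it ran from 258 (without replicate 1 of INA-6 alone) to 3660 (without the INA-6 line) when arrays or lines were left out. Replicate numbers were not taken as pairs, since the deviations correlated at 0.408 in MM.1S and 0.581 in MM.1R but 0.0795 in INA-6, and the block gave 4484, 1680 and 7871 for MM.1S, MM.1R and INA-6.

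With all tested probe sets, where more features are tested, the counts were 10465 for MM.1S, 4978 for MM.1R, 17026 for INA-6, 11684 for the F-test and 2167 at 2-fold. Leaving out an array gave 2918 to 7897 for MM.1S, 1066 to 5501 for MM.1R, 5628 to 10163 for INA-6 and 3273 to 9464 for the F-test. The 2-fold count of 1048 ran from 976 (without replicate 2 of INA-6 alone) to 2296 (without MM.1R) when arrays or lines were left out, was 1761 without INA-6, and was 814 after quantile normalization, 833 with centring, 883 with the pseudocount at the 40th percentile and 931 with the filter at the 75th. Without the INA-6 arrays MM.1S passed 7582 and MM.1R 5134. The duplicates of INA-6 alone, at 0.839, widen the shared spread, and among left-out arrays the highest counts of the line fits came without 1 of them.

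Of the 10 lists that passed, 0 did with an estimated correlation, at unchanged medians: cytokines 3.83, immediate-early 1.75, hypoxia 1.59, interferon 1.33, stromal 1.22, glucocorticoid 1.13, apoptosis 0.81, STAT3 0.50, NF-kB 0.44, cholesterol -0.44. Fry, which tests against no change and not against other genes, passed 9, without apoptosis (0.81, adjusted p = 0.0593). With the filter at the 75th percentile the STAT3 response (0.27, adjusted p = 0.0717) and NF-kB (0.14, adjusted p = 0.116) lost their calls, MYC targets (-0.42) gained 1, and cell cycle (-0.031), plasma cell (-0.038) and unfolded protein response (-0.025), not called, changed sign. Quantile normalization gave MYC targets a call (-0.25) and turned the Notch median (0.034). Without the filter, MHC class I (0.67) and the unfolded protein response (0.46) were called, and MYC (0.037), adhesion (0.043) and Notch (0.11), not called, changed sign. Over left-out lines the medians ran from 0.036 to 0.91 for MHC class I (called without INA-6), -0.35 to -0.0034 for MYC (called without MM.1S), -0.070 to 0.51 for plasma cell, -0.31 to 0.87 for the unfolded protein response (called without INA-6), -0.41 to 0.35 for adhesion and -0.18 to 0.056 for Notch, the lists that changed sign not being called where they did. Unless stated, the cause was not tested. Signal over background limits dim genes: 3.02% to 3.63% of values stood at the floor of 1.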

Other observations

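Changes in other members of the lists add detail to the lines. MM.1S and MM.1R shared 1709 genes higher and 316 lower after coculture. MCL1, an anti-apoptotic protein on which myeloma cells depend, rose by 1.86 in MM.1S, 1.13 in MM.1R and 1.34 in INA-6, and stood at 1.45 in the common test without passing (adjusted p = 0.0920). MYC rose by 1.05 in MM.1S and 1.11 in MM.1R, and stood at -0.20 in INA-6 without passing. The kinase PIM1, induced by STAT3, rose by 2.20 in MM.1S and 3.53 in INA-6 and stood at 1.11 in MM.1R without passing. The death effector BAX rose by 2.74 in MM.1S and 3.16 in INA-6 and stood at 0.73 in MM.1R without passing. TSC22D3, a glucocorticoid-induced leucine zipper protein, rose by 4.48 in INA-6 and stood at 1.65 in MM.1S and 1.88 in MM.1R without passing. SLAMF7, a surface marker of plasma cells, fell by 2.43 on the log2 scale in INA-6 and stood at -0.40 in MM.1S and -0.25 in MM.1R without passing. Other probe sets of MCL1 had common changes down to -0.43, and another of TSC22D3 stood at -0.50. These genes were chosen after their values were seen, and the differences between the lines in them are not tested here.

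The averaged profile of INA-6 after coculture correlated across genes at 0.898 with MM.1S and 0.895 with MM.1R after coculture, and at 0.762 with INA-6 alone. With MM.1S alone and MM.1R alone it correlated at 0.801 and 0.850. The profile of INA-6 alone correlated at 0.667 to 0.712 with the groups of MM.1S and MM.1R. MM.1S and MM.1R correlated at 0.957 alone and at 0.988 after coculture. Genes are not independent replicates.

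The deviation of an array from the mean of its group, taken for replicate 1, correlated across genes at 0.408 between the groups of MM.1S and at 0.581 between those of MM.1R. Between MM.1S and MM.1R it was -0.469 for cells alone and -0.505 for coculture. In INA-6 it was 0.0795.

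The immediate-early and heat-shock genes raised at least 4-fold in MM.1S and MM.1R, 12 in number, had a median log2 ratio of the coculture excess between MM.1R and MM.1S of 0.712, against 0.989 for the 388 genes of all kinds so raised.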
